A study of Mus musculus with 4 samples.

How the data were processed

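RNA from the colon epithelium of 4 mice was measured on 4 arrays. All mice carried floxed alleles of Stat3 (loxP sites flank part of the gene, so that Cre recombinase removes it). In 2 of them a Cre recombinase driven by the villin promoter, which is active in intestinal epithelial cells, was present (Cre-positive), and in the other 2 it was absent (Cre-negative). All 4 mice had received 2.5% dextran sodium sulphate (DSS), a polymer that injures the colon epithelium, in the drinking water for 5 days. No array of an untreated mouse was analysed here. Total RNA was purified on columns with DNA digestion and biotin-labelled cRNA was made by the Affymetrix protocol, per the labels' protocols. Array type, scanner settings and how the epithelium was separated from the rest of the colon wall are not given in the sources used here.

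The authors' values were GC-RMA intensities, per the submitters' processing notes and the file headers. GC-RMA subtracts a background that depends on the GC content of each probe, makes the intensity distributions of the arrays alike and combines the probes of a probe set into 1 value. It leaves transcripts without detectable signal in a narrow band at the bottom of the scale. The deposited intensity values of the series ranged over 45101 probe sets and were on the linear scale. A second table by the authors held the same intensity values rounded to whole numbers, log2 values, a fold change and a p-value for each probe set. Tested against the first table, the rounded intensities differed by at most 0.5. The authors' log2 values equalled log2 of the intensity minus the mean of the Cre-negative arrays to within 0.000502. The authors' absolute fold, a ratio, equalled 2 to the power of the difference of mean log2 values to within 0.005. The authors' p-values, whose test is not named in the file headers, matched an equal-variance test of the group means on log2 values to within 9.3e-05.

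Probe sets were named through a given table that pairs them with gene symbols. Apart from 64 control probe sets, 34945 probe sets had 1 gene, 932 had several genes and were not named, and 9160 are unnamed here. Gene identifiers of 34741 probe sets matched the reference gene table, and 534 of the 580 genes in the lists described below were matched. For each of the 18193 genes the probe set with the highest mean over the 4 arrays was used. Genes at or below the 40th percentile of all probe sets' means (log2 2.81, intensity 6.99) were left out, which left 12659 genes. Of the 5796 tested genes with several probe sets, 2474 had at least 1 probe set with a difference in the opposite direction, among them Stat3, Cmah, Ttc6, Jak1, Cd44, C1qb, Kit, Insyn2a, Cflar and Xiap. Some probe sets (those with s or x in their identifiers) can bind transcripts of related genes.

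Differences are Cre-positive minus Cre-negative on the log2 scale. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided) and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. All adjusted p-values of single genes come from this fit, and SE is its moderated standard error. There were 2 residual degrees of freedom, and the variance prior added 1.58. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333. The number of arrays limits the precision of every value. The labels name the arrays biological replicates from separate mice.

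Before the data were examined, 32 gene lists were fixed: epithelial cell types, signalling, inflammation, metabolism, stress and growth, markers of other cell types, and housekeeping genes. Lists with at least 5 tested genes (26 lists) were tested with limma's camera, a test of whether a list's genes stand higher or lower than the other genes, with its preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. An estimated correlation in camera and limma's fry were alternatives. With an estimated correlation the smallest unadjusted camera p of any of the 26 lists was 0.096. Correlation was not the only reason. For xenobiotic and redox genes it was estimated at -0.039, below the preset, yet camera's unadjusted p rose from 0.00875 to 0.103. A call lost under this alternative therefore does not tell whether the list changed. Genes named by rule were Stat3, then, since no gene passed the threshold, the 8 genes of smallest unadjusted p in each direction, and from each list the 2 genes of smallest unadjusted p. Other named genes, among them those with the largest differences, were chosen after their values were seen. The 5-prime and 3-prime control probe sets of Actb and Gapdh gave a measure of RNA quality.

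The fit was tested on simulated data with 200 of the 12659 genes changed in 20 runs. With noise as estimated from the arrays, the share of changed genes recovered was 0.208 at a log2 difference of 1, 0.548 at 2, 0.747 at 3 and 0.839 at 4, with 5.1 false calls per run. With every gene given the variance of the prior at its intensity, without extra spread between genes, the share was 0.98 at 1 and 1 at 2 to 4, with 8.45 false calls per run. Camera called a simulated list of independent genes raised by 1 in 20 of 20 runs, with 1 false list call in all, and made 0 calls when no list was raised. In the data the genes of a list were not independent. The estimated correlation was 0.807 for interferon-stimulated and 0.937 for MHC class II genes. These false-call counts therefore do not carry over to such lists. Alternatives covered the filter on dim genes, the variance prior, the scaling between arrays, the authors' log2 table, the choice of probe set, a replicate block and leaving out each array in turn, where the lone array of a group is assumed to vary like the pair in the other group. Alternatives added after seeing the data were no filter with a robust prior, the same with quantile normalization, quantile normalization for the lists, and counts at an unadjusted p under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.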

Results

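Gene expression was measured in the colon epithelium of 4 mice after 5 days of 2.5% DSS, with 1 array for each mouse. In the 2 Cre-positive mice the villin-driven recombinase was present together with floxed Stat3 alleles, and in the 2 Cre-negative mice it was absent. Stat3 encodes a transcription factor that is activated by cytokines such as interleukin 6, interleukin 10 and interleukin 22. The median intensity over 45101 probe sets lay between 9.14 and 9.42 in the 4 arrays. The ratio of 3-prime to 5-prime signal was 1.27 to 1.42 for Actb and 0.782 to 0.992 for Gapdh. Correlations between arrays over all genes tested ranged from 0.981 to 0.994, and Cre-positive array 1 stood farthest from the others. The arrays did not group by genotype: Cre-positive array 2 correlated at 0.992 and 0.994 with Cre-negative arrays 1 and 2, and at 0.984 with Cre-positive array 1.

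The first question was whether the targeted gene differed between the groups. By its brightest probe set, Stat3 transcript was lower in both Cre-positive mice than in either Cre-negative mouse. This probe set measured log2 8.72 ± 0.79 (SD, n = 2) in the Cre-positive group and 10.48 ± 0.03 (SD, n = 2) in the Cre-negative group. The difference of -1.75 (SE 0.43) is 3.37-fold and did not pass the threshold (limma adjusted p = 0.332). Another probe set showed -1.57, whereas one more went the other way, at log2 6.47 ± 0.51 against 5.17 ± 0.60 (SD, n = 2 per group), a difference of 1.29. The last of the 4 probe sets lay at the bottom of the scale in all arrays. Whether any of these probe sets lies in the deleted part of the gene is not known from the labels, so they do not settle how much of the gene was removed. The difference was -2.31 without Cre-positive array 1 and -1.20 without Cre-positive array 2, and the mean of all its probe sets gave -0.53.

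Among the genes that stood lowest in the Cre-positive epithelium, picked after their values were seen, were Reg3g (-3.26), Reg3b (-2.83), Gatm (-2.40, at log2 3.73 and 5.48 in the Cre-positive arrays), Tifa (-2.38), Pla2g5 (-1.96), Socs3 (-1.77) and Tac1 (-1.54). Lrg1, a secreted acute-phase glycoprotein gene, measured log2 5.90 ± 1.41 (SD, n = 2) in the Cre-negative group and lay at the bottom of the scale in both Cre-positive arrays (2.85 and 2.57), and Fut9 measured 5.58 ± 0.01 and lay there in Cre-positive array 1 (2.63, with 3.97 in array 2), so no size is given for their differences. Pla2g2a fell from 5.75 ± 0.69 to close to the bottom of the scale (3.24 and 3.62) and has no size for the same reason. Tifa encodes an adaptor in NF-kappaB signalling, Gatm an enzyme of creatine synthesis and Tac1 the precursor of substance P. At the upper end stood the interferon-induced Ifi27l2a (2.19) and Krt12 (1.97, at log2 3.98 and 3.71 in the Cre-negative arrays). Ang4, an antimicrobial ribonuclease of the gut (2.32, with the Cre-negative arrays apart at log2 9.45 and 11.26), and Insyn2a (2.20, with 1 other probe set going the other way) stood there too. Further genes there stood higher in Cre-positive array 1 than in array 2: Nlrc5, a transactivator of MHC class I genes (7.77 and 5.94), Sbno2 (6.71 and 5.29), Mx1 (7.33 and 5.87) and Hoxb5 (6.84 and 5.67). All the genes named here were picked among those at an unadjusted p under 0.05 in which both Cre-positive arrays lay on 1 side of both Cre-negative arrays. That separation was therefore a condition of the choice and not a result. Genes with overlapping groups, such as Cxcl2 (2.60), were left out by it.

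No gene passed the threshold by itself. Limma called 0 genes higher and 0 lower after adjustment over 12659 genes, with a smallest adjusted p of 0.244, while 322 genes were higher and 1077 lower at an unadjusted p under 0.05, where 633 would be expected in all. Of the 1077 lower genes, 832 lay at or below the 60th percentile of intensity. With arrays centred on their medians the unadjusted split was 329 higher and 610 lower. At a difference of at least 1 on the log2 scale and an unadjusted p under 0.05, 41 genes were higher and 33 lower. The groups did not overlap in 1715 higher and 4397 lower genes, 48.3% of those tested against 33.3% by chance. Chance splits evenly between the directions, so the higher genes were fewer than by chance and the whole excess lay on the lower side. Leaving out Cre-positive array 2 gave 1182 genes higher and 2188 lower at the unadjusted threshold, and the number higher was 545 without Cre-positive array 1, 155 without Cre-negative array 1 and 114 without Cre-negative array 2.

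The genes with the smallest unadjusted p in each direction, none past the threshold (limma adjusted p = 0.244 for each), covered a wide range of intensity. Among the higher ones Ifi27l2a went from log2 8.89 ± 0.29 to 11.08 ± 0.08 (SD, n = 2 per group), and Mt1, a metallothionein that binds zinc and copper, from 12.34 ± 0.34 to 14.05 ± 0.10. Krt12, a keratin, was higher by 1.97, from a low level in the Cre-negative arrays (log2 3.98 and 3.71). By their brightest probe sets Cmah, an enzyme of sialic acid metabolism, was higher by 1.03 and Ttc6 by 0.79. Of the probe sets above the filter, 2 of 4 for Cmah and 1 of 2 for Ttc6 went the other way. The transporter gene Slc29a4 was higher by 0.53. Zfp653 and Fbf1 stood at or close to the bottom of the scale in the Cre-negative arrays and so have no size. Among the lower ones Pla2g5, a secreted phospholipase A2, went from 8.87 ± 0.14 to 6.91 ± 0.15, and Gna14, a G protein subunit, from 10.55 ± 0.08 to 9.44 ± 0.01. Rasl2-9 differed by -0.99 and Tac1 by -1.54. Apobec2, Spic, Klrb1b and Dcaf12l1 were lower too, but lay close to the bottom of the scale in the Cre-positive arrays (log2 3.13 to 3.54), so no size is given for them. Zfp653, Slc29a4, Fbf1, Ttc6, Spic, Apobec2, Dcaf12l1 and Klrb1b were dim, with group means under the 60th percentile of intensity.

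**Figure D1:**
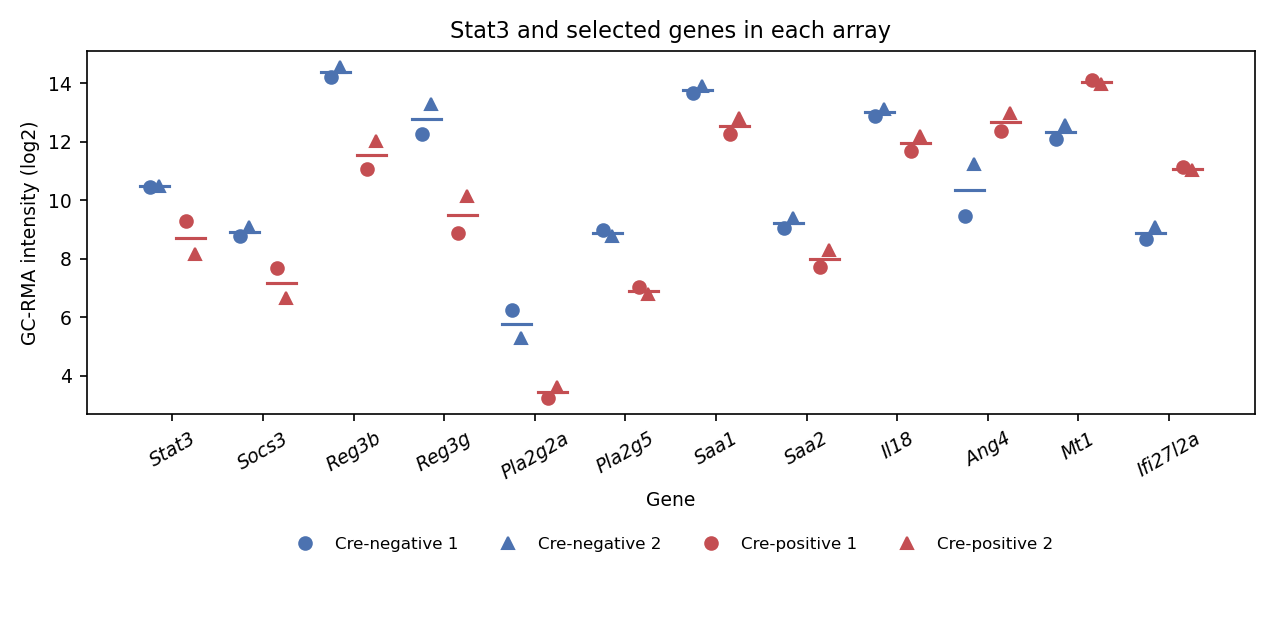
Log2 GC-RMA intensity of Stat3 and 11 other genes, chosen after their values were seen, in each array (points, blue Cre-negative, red Cre-positive, circles replicate 1, triangles replicate 2) with the group mean (bar). Both Cre-positive arrays lie below both Cre-negative arrays for Stat3 and 8 genes and above them for Ang4, Mt1 and Ifi27l2a, and Reg3b averages 14.38 in the Cre-negative and 11.55 in the Cre-positive group.

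Antimicrobial and acute-phase genes were the list with the lowest median. Of 22 genes tested, 17 had a lower and 5 a higher mean in the Cre-positive group, with a median difference of -0.41. Over all genes 0 of them passed in limma, 7 were under 0.05 unadjusted, and adjusted over the list alone 5 passed, all lower. These were Reg3b and Reg3g, C-type lectins that act on gut bacteria, the secreted phospholipases Pla2g2a and Pla2g5, and the serum amyloid Saa1 (-1.25). Reg3b measured log2 11.55 ± 0.68 against 14.38 ± 0.25 and Reg3g 9.51 ± 0.90 against 12.77 ± 0.72 (SD, n = 2 per group). Another Reg3b probe set, of a kind that can bind transcripts of related genes, differed by -4.39. Saa2 (-1.22), Fut2 (-0.70) and Lbp (-0.89) also lay lower in both Cre-positive arrays, whereas Ang4 (2.32) and the lysozyme gene Lyz1 (0.94) lay higher in both. As a set the list did not pass camera (adjusted p = 0.0932, and adjusted p = 0.723 with an estimated correlation), and fry's directional test gave an adjusted p of 0.401, while fry's test for change in either direction gave 0.00747, the same value as for the fibroblast markers. The camera call was reached without Cre-negative array 1 (adjusted p = 0.0139), without Cre-positive array 1 (adjusted p = 0.0488) and under 5 other settings, but not without Cre-negative array 2 (adjusted p = 0.405), without Cre-positive array 2 (adjusted p = 0.472) or without the filter on dim genes (adjusted p = 0.649). The median was -0.60 without Cre-negative array 1 and -0.15 without Cre-negative array 2, where heat shock (-0.37) and cholesterol synthesis genes (-0.35) had lower medians.

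The list of STAT3 target genes, which shares no gene with the antimicrobial list, was not called as a set. Of 18 tested, 10 were lower and 8 higher, 0 passed over all genes in limma, 0 passed adjusted over the list alone, and 4 were under 0.05 unadjusted, all lower. Those 4 were Socs3 (-1.77, log2 7.16 ± 0.72 against 8.93 ± 0.22, SD, n = 2 per group), the feedback inhibitor of cytokine signalling, Cebpd (-1.0), Ccnd1 (-0.43) and Icam1. Icam1 lay close to the bottom of the scale in all arrays (log2 3.03 to 3.55), so no size is given for it. All 3 Socs3 probe sets were lower, another by -1.26, and the third, at log2 4.92 and 5.64 in the Cre-negative arrays, lay at the bottom of the scale in the Cre-positive arrays. Camera gave an adjusted p of 0.978 for this list. The list was fixed beforehand and may miss genes that STAT3 acts on, so it does not speak for all such genes. Whether the antimicrobial genes are among them was not tested. Cytokine receptors and JAK-STAT components showed 11 of 21 genes higher and a median of 0.0053, with Stat2 (0.89) and Jak1 (0.31) at the smallest unadjusted p (camera adjusted p = 0.123, but 0.0400 without Cre-negative array 2 and 0.0213 without the filter on dim genes). Among inflammatory cytokines and chemokines Il18, made by epithelial cells, was lower by -1.07 (11.95 ± 0.38 against 13.02 ± 0.17, SD, n = 2), with 10 of 15 genes lower and a camera adjusted p of 0.618. Cxcl5 was lower too, but lay close to the bottom of the scale in all arrays (log2 3.38 to 3.67). The largest differences among these cytokines were higher, Cxcl2 (2.60) and Il1b (1.57), with groups that overlapped. In both lists 0 genes passed over all genes in limma and 0 adjusted over the list alone, with 2 under 0.05 unadjusted in each.

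Interferon-stimulated genes were higher as a group. Of 30 tested, 29 had a higher mean in the Cre-positive group, and the median difference was 1.04. The differences included Ido1 (2.49), which degrades tryptophan, the antiviral Mx1 (1.90) and Oas2 (1.84), the chemokine Cxcl10 (1.66), the GTPase Iigp1 (1.48) and the regulator Irf7 (1.10, log2 10.90 ± 0.52 against 9.80 ± 0.09, SD, n = 2), and Irf8 (-0.22) was the exception. By itself 0 of these genes passed over all genes in limma, 0 passed adjusted over the list alone, and 3 were under 0.05 unadjusted. Camera called the list (adjusted p = 5.41e-10), and the call was lost with an estimated correlation (adjusted p = 0.723 with an estimated correlation), as was every other list call. The correlation between its genes, estimated from the replicates, was 0.807. The median was 1.66 in Cre-positive array 1 and 0.30 in Cre-positive array 2 against the mean of the Cre-negative arrays. T and NK cell markers had medians of -0.03 and 0.39 in these arrays. The neutrophil markers S100a8 and S100a9 and the macrophage list also stood higher in Cre-positive array 1 than in array 2.

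**Figure D2:**
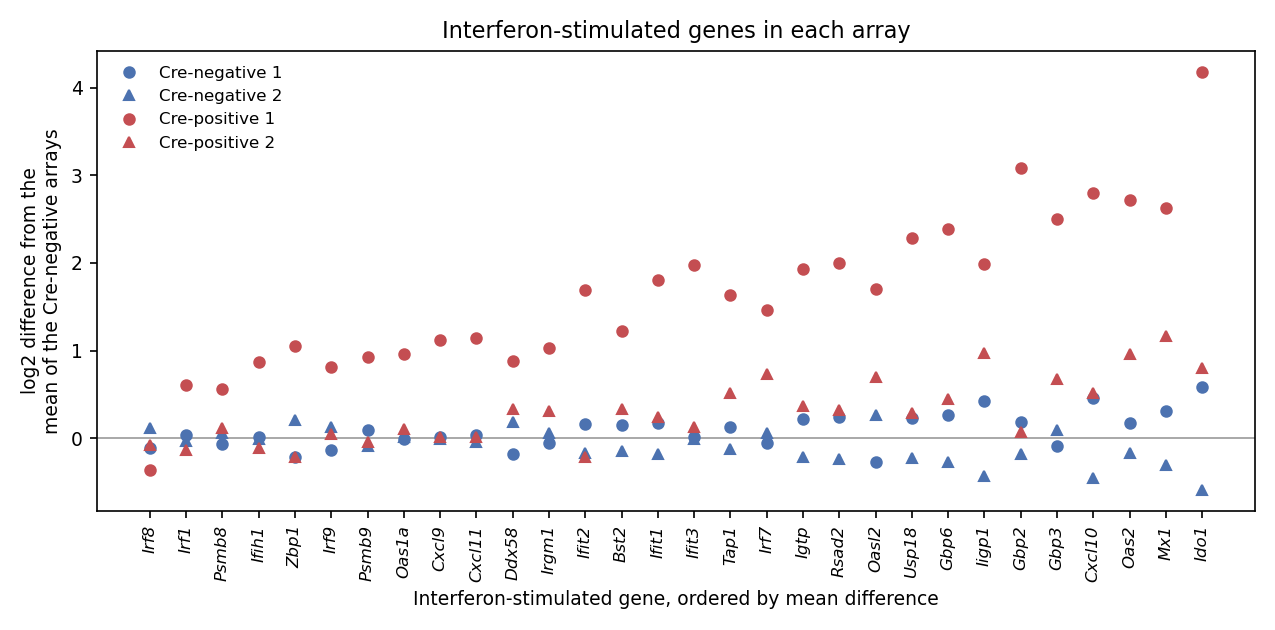
Difference of each array from the mean of the Cre-negative arrays (vertical axis, log2) for 30 interferon-stimulated genes (horizontal axis, ordered by mean difference; blue Cre-negative, red Cre-positive, circles replicate 1, triangles replicate 2). Cre-positive array 1 lies above Cre-positive array 2 in 29 genes, with medians of 1.66 and 0.30.

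MHC class II genes, which present antigen to T cells, were higher in 5 of 5 genes with a median of 0.59, and with 0.54 in Cre-positive array 1 and 0.78 in array 2. Macrophage and monocyte markers, whose cells also present antigen, had a median of 0.41 (8 of 12 higher), with 0.46 in Cre-positive array 1 and -0.03 in array 2. T and NK cell markers had -0.03 and 0.39 in these arrays. H2-Aa differed by 0.91 and Cd74, the invariant chain, by 0.86. Adjusted over the list alone 0 passed, as over all genes in limma, and 1 was under 0.05 unadjusted. Camera called this list (adjusted p = 0.00651), which was lost with an estimated correlation (adjusted p = 0.723 with an estimated correlation) and without Cre-positive array 2 (adjusted p = 0.101). The Cre-negative arrays differed from each other (H2-Aa at log2 9.52 and 8.75), and the median was 0.97 without the first and 0.30 without the second.

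Genes of mature colon epithelium had slightly positive medians, as did pan-epithelial markers (0.15, 10 of 13 higher, but 0.21 in Cre-positive array 1 and 0.0022 in array 2). Absorptive colonocyte genes had a higher mean in 20 of 25, with a median of 0.18, and 0.25 and 0.11 in Cre-positive arrays 1 and 2. Examples were Muc3 (0.59), a membrane mucin, the sodium-proton exchangers Slc9a2 (0.33) and Slc9a3 (0.81), and Scnn1b (-0.68) went the other way. Goblet cell genes were higher in 12 of 18 (median 0.09), among them Fcgbp (0.56) and Muc2 (0.42), the main gel-forming mucin. Tight junction and adhesion genes were higher in 14 of 20 (median 0.13), with Cgn at 0.44, Tjp1 at 0.36 and Cldn1 at the bottom of the scale in both groups, and a median of -0.039 in Cre-positive array 2. Xenobiotic and redox genes were higher in 12 of 21 (median 0.09), with the efflux pump Abcb1a at 0.53 and Aldh1a1 at 0.39. In Cre-positive array 1 the goblet cell and xenobiotic medians were 0.0066 and 0.011. In these 4 lists 0 genes passed over all genes in limma or adjusted over the list alone, against 2, 2, 3 and 1 under 0.05 unadjusted. Camera called all of them, with adjusted p = 0.000287, 0.0379, 0.0469 and 0.0379 in that order, and called none with an estimated correlation (adjusted p = 0.723 with an estimated correlation for each). Camera weighs a list against the other genes, and the median over all genes tested was -0.053. With medians this small, a call need not mean that the list itself rose. Above the 60th percentile of intensity the absorptive colonocyte call remained (adjusted p = 0.000933) and the other 3 were lost (0.0684, 0.0684 and 0.0981), and these 3 were also lost without at least 1 single array, goblet cell genes without Cre-negative array 1 (0.20), tight junction genes without Cre-positive array 1 (0.812) and xenobiotic genes without Cre-positive array 2 (0.361).

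The remaining epithelial, stress and metabolic lists did not pass camera. Cell cycle genes were higher in 17 of 30, with Cenpe at 0.54 and Mki67 at 0.45 (adjusted p = 0.123). Crypt stem cell and Wnt target genes had a median of -0.10, with Cd44 at 0.42 and Ephb3 at -0.31 (adjusted p = 0.749). Enteroendocrine genes included Insl5 (-0.58) and Chga (0.53) (adjusted p = 0.978), and tuft cell genes Rgs13 (-0.30) and Alox5ap (0.28) (adjusted p = 0.363). Among wound repair genes Smo, a transducer of hedgehog signals, differed by -1.04 and Mmp7 by -0.25 (adjusted p = 0.0932). Apoptosis regulators included Cflar (0.60) and Xiap (0.52), inhibitors of caspase activation, by their brightest probe sets, while 3 of 5 and 4 of 7 probe sets went the other way (adjusted p = 0.470). Heat shock genes included Hspe1 (-0.19) and Dnajb4 (-0.20) (adjusted p = 0.978), unfolded protein response genes Syvn1 (0.43) and Pdia4 (-0.40) (adjusted p = 0.134), and cholesterol synthesis genes Mvd (-0.44) and Lss (-0.26) (adjusted p = 0.978). Fatty acid oxidation genes included Cpt2 (0.31) and Cd36 (at the bottom of the scale in the Cre-positive arrays) (adjusted p = 0.0932), and hypoxia and glycolysis genes Hk2 (0.62) and Bnip3 (-0.36) (adjusted p = 0.134). Cell cycle, wound repair, unfolded protein response, fatty acid oxidation and hypoxia genes did pass camera without the filter on dim genes and without at least 1 of the arrays. In all of these, 0 genes passed over all genes in limma, and adjusted over the list alone only Cd36, a dim gene, passed. The numbers under 0.05 unadjusted ranged from 0 to 1 per list. Median and camera direction had opposite signs for STAT3 targets, crypt stem cell, enteroendocrine, apoptosis and housekeeping genes, with medians of -0.10 to -0.06, and for inflammatory cytokines the mean (0.12) and the median (-0.08) did. Camera's direction is relative to the other genes, and the median over all genes tested was -0.053. It can therefore be higher for a list that did not rise, and all 8 lists that camera called were called higher.

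**Figure D3:**
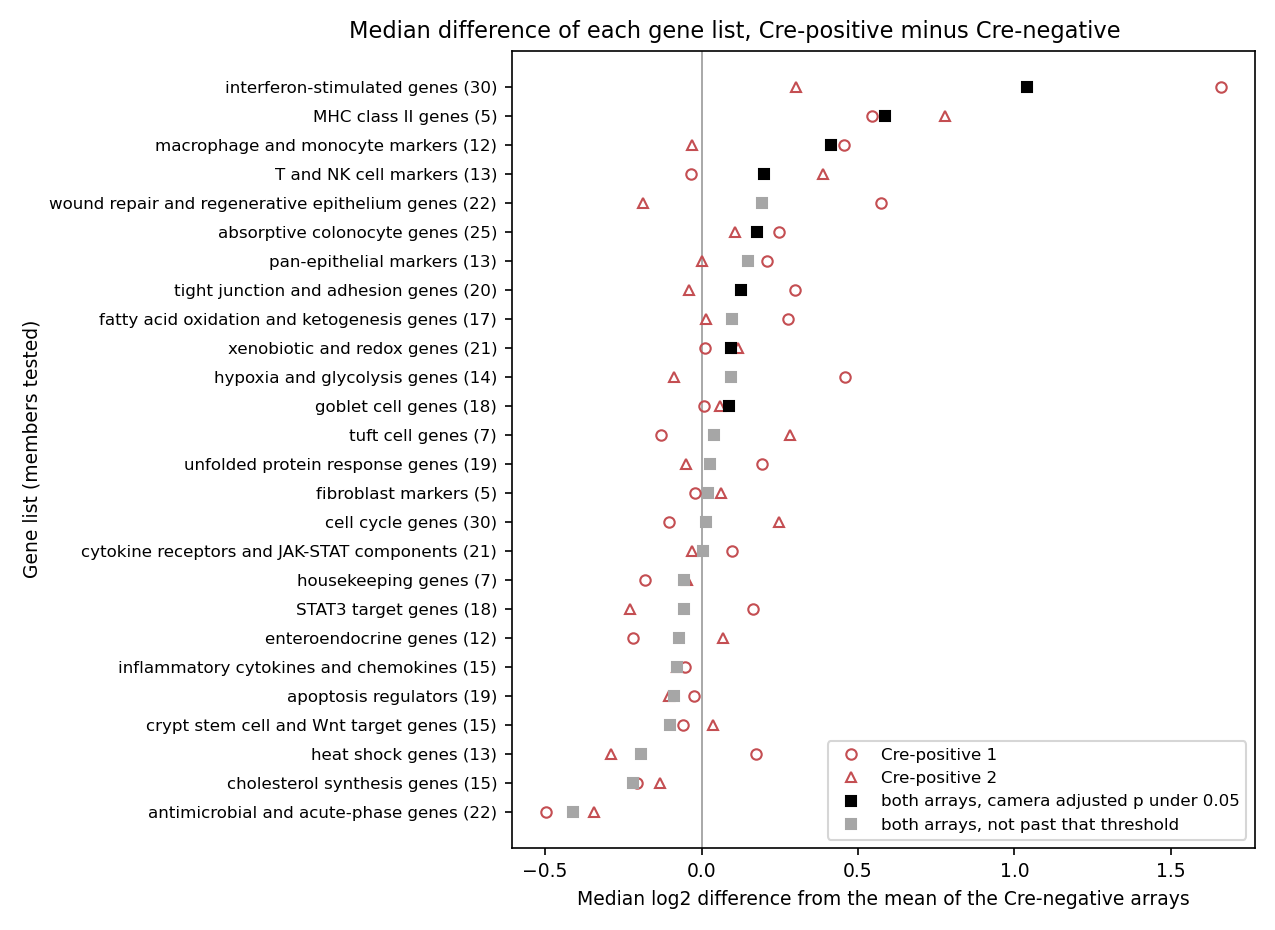
Median log2 difference from the mean of the Cre-negative arrays (horizontal axis) for the genes of 26 lists (vertical axis, number tested in brackets), over both Cre-positive arrays (squares, black where camera passed with its preset correlation) and for each Cre-positive array (open circle 1, open triangle 2). Over both Cre-positive arrays, interferon-stimulated genes have the highest median (1.04) and antimicrobial and acute-phase genes the lowest (-0.41). In Cre-positive array 2 alone, MHC class II genes (0.78) and T and NK cell markers (0.39) lie above interferon-stimulated genes (0.30).

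Markers of other cell types that such a preparation could hold differed between individual arrays. Pan-epithelial markers had a median of 0.15, with Epcam at 0.17 and Elf3 at -0.17 (camera adjusted p = 0.0607, and 0.00399 without Cre-positive array 2). The neutrophil markers S100a8 and S100a9 stood at log2 9.70 and 9.46 in Cre-positive array 1 and at 5.06 and 4.60 in Cre-positive array 2, with a Cre-negative mean of 5.35 for S100a8. Trem1 lay close to the bottom of the scale except in Cre-positive array 1 (log2 4.15), so no size is given for it. In all, 4 neutrophil genes were tested. Macrophage and monocyte markers were higher in 8 of 12 (median 0.41), among them the complement genes C1qb (0.48) and C1qa (0.87), with array medians of 0.46 and -0.03. T and NK cell markers were higher in 10 of 13 (median 0.20), with Thy1 at 0.38, Cd4 at the bottom of the scale in the Cre-positive arrays and array medians of -0.03 and 0.39. Camera called both lists (adjusted p = 0.0379 and 0.0488), and neither with an estimated correlation (adjusted p = 0.723 with an estimated correlation for each). The macrophage call was lost without Cre-positive array 1 (adjusted p = 0.851) and the T and NK cell call without Cre-positive array 2 (adjusted p = 0.817).

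Few stromal markers stood well above the bottom of the scale, with 1 of 5 fibroblast genes, Vim, above the 60th percentile of intensity. Fibroblast markers included Vim (0.66) and Thy1 (0.38), which T cells share, with a median of 0.02 over 5 genes (camera adjusted p = 0.135). The smooth muscle, neural, endothelial, B cell and mast cell lists had fewer than 5 genes tested. Myh11 (smooth muscle), Tubb3 (neural), Eng (endothelial), Ms4a1 (B cell) and Tpsb2 (mast cell) lay close to the bottom of the scale throughout (log2 2.97 to 3.54). No size is given for these genes. Synm (smooth muscle) lay at the bottom of the scale in both groups, and Jchain (B cell) except in Cre-positive array 1. The neural gene Sox10 differed by -0.26 and the mast cell gene Kit by 0.24. Housekeeping genes included B2m (0.27) and Gusb (-0.44), with a median of -0.06 over 7 genes (camera adjusted p = 0.832). None of the genes in these lists passed over all genes in limma. Adjusted over the list alone, Thy1 passed in the T and NK cell and the fibroblast lists (higher), and Myh11 in the smooth muscle and Tubb3 in the neural list (lower). Thy1 was dim, and Myh11 and Tubb3 lay close to the bottom of the scale, where dim genes as a group were slightly lower. Unadjusted, 2 fibroblast genes, 2 T and NK cell genes, 1 macrophage gene, 1 smooth muscle gene and 1 neural gene were under 0.05.

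The authors' deposited table gave a p-value under 0.05 to 12636 of the probe sets, 28.0%, of which 95.4% were lower in the Cre-positive group. The share depended on intensity. In the authors' deposited table it was 58.1% in the lowest of 5 equal bands of mean intensity and 4.76% in the highest. After Benjamini-Hochberg adjustment of the same equal-variance test, 1 probe set remained, with an adjusted value of 0.0123.

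**Figure D4:**
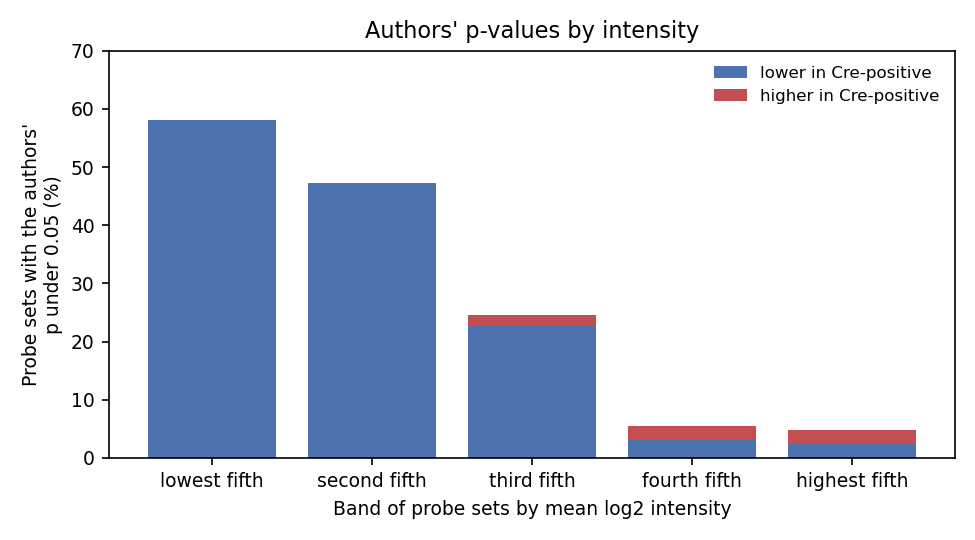
Percentage of probe sets with a p under 0.05 in the authors' deposited table (vertical axis) in each of 5 bands of mean log2 intensity (horizontal axis), split into lower (blue) and higher (red) in the Cre-positive group. The bar falls from 58.1% in the lowest to 4.76% in the highest band, and nearly all of these in the lowest band are lower.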

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

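The counts at an unadjusted p, the lists with quantile normalization and the combined settings without a filter were chosen after the data were seen; the other alternatives were fixed before the data were examined. No gene passed in any alternative fixed beforehand, so the side of the threshold could not change there. Over all settings, 1848 of 1885 pairs of a named gene and a setting kept direction and side of the threshold, and 12 reversed. Many named genes had groups that did not overlap, and such a gene cannot reverse with 1 array left out. The count is therefore no measure of robustness. Without a filter and with a robust prior, 29 genes were higher and 2067 lower after adjustment (5473 lower unadjusted), but 0 and 0 once quantile normalization was added (1749 lower unadjusted). Lower genes at an unadjusted p under 0.05 numbered 5319 without a filter, 259 above the 60th percentile, 583 without the intensity trend, 610 with centred medians and 2280 over probe sets (911 higher), and 844 to 2188 with 1 array left out (114 to 1182 higher). The filters act through the number of dim genes tested, and other causes were not tested. One Stat3 probe set went the other way (1.29). With 1 array left out, these genes crossed 0, with ranges of -0.46 to 0.073 for Dnajb4, -0.026 to 0.99 for Trem1, -0.29 to 4.35 for S100a8, -0.39 to 4.47 for S100a9, -0.19 to 3.75 for Ptgs2, -0.084 to 0.96 for Jchain, -0.054 to 0.033 for Eng and -0.081 to 0.56 for Kit. Eng was 0.0081 after quantile normalization, with and without the filter, and Kit -0.047 as the mean of its probe sets. Lists called numbered 0 with an estimated correlation, 0 with fry's directional test (2 with its test for either direction), 18 without a filter, 5 above the 60th percentile, and 5 to 9 with 1 array left out. Whether the replicate numbers mark anything shared is not known from the labels. As a replicate block they gave 13 lists and moved the antimicrobial list to an adjusted p of 0.0285, and the deviations of the 2 pairs correlated at 0.423 over genes. The 8 called lists all went to 0.723 with an estimated correlation. With fry they went to 0.866, except absorptive colonocyte (0.401) and xenobiotic genes (0.444). Above the 60th percentile, goblet cell and tight junction genes were at 0.0684 and xenobiotic genes and T and NK cell markers at 0.0981. After quantile normalization macrophage markers were at 0.109 and T and NK cell markers at 0.104. The antimicrobial list passed above the 60th percentile (0.0105), with centred medians (0.0280), with mean probe sets (0.0378) and after quantile normalization (0.0243). Adjusted p ranges with 1 array left out were 0.0139 to 0.472 for the antimicrobial list, 4.12e-06 to 0.101 for MHC class II, 0.00464 to 0.20 for goblet cell, 0.00351 to 0.812 for tight junction, 0.00826 to 0.361 for xenobiotic genes, 0.000367 to 0.851 for macrophage and 0.00111 to 0.817 for T and NK cell markers. Lists not called could turn direction. For STAT3 targets this gave 0.866 (fry), 0.914 (60th percentile), 0.815 (centred), 0.653 (mean probe sets), 0.935 (quantile) and 0.115 to 0.971 with 1 array left out. For cytokines it gave 0.721 (no filter), 0.945 (60th percentile) and 0.0934 to 0.940, for crypt genes 0.950 (fry), 0.914 (60th percentile), 0.934 (mean probe sets) and 0.115 to 0.763, and for enteroendocrine genes 0.950 (fry), 0.945 (60th percentile), 0.996 (centred) and 0.420 to 0.780. It gave 0.866 (fry) and 0.148 to 0.985 for apoptosis regulators, 0.429 (no filter), 0.934 (mean probe sets) and 0.0760 to 0.293 for heat shock genes, 0.243 (no filter), 0.801 (mean probe sets) and 0.0934 to 0.985 for cholesterol genes, 0.909 (no filter) for fibroblast markers, and 0.950 (fry), 0.945 (60th percentile) and 0.424 to 0.985 for housekeeping genes. With 1 array left out only, the range was 0.000999 to 0.641 for cell cycle, 0.0892 to 0.938 for tuft cell, 0.000361 to 0.420 for wound repair, 0.0361 to 0.985 for unfolded protein response and 0.0153 to 0.985 for hypoxia genes.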

Other observations

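The tests that weigh the 3 patterns below were chosen only after the results were seen, though leaving out an array and quantile normalization of single genes were settings fixed before, and the gene families were picked after their values were seen. The 3 genes with a Wfdc symbol (for whey acidic protein domain) above the 60th percentile of intensity were lower in both Cre-positive arrays than in both Cre-negative arrays. Wfdc18 differed by -1.44, Wfdc17 by -1.28 and Wfdc2 by -0.30. Genes with such a domain under other symbols were not included. Of 3 metallothionein genes, Mt1 was higher in both of its probe sets, by 1.71 in the brighter one, and Mt2 (1.23) and Mt3 (-0.05) had groups that overlapped. Of 3 schlafen genes, Slfn4 (2.01) and Slfn2 (1.57) were higher and Slfn9 (-0.18) lower. Of 5 guanylate-binding protein genes 4 were higher without overlap, with medians of 2.38 in Cre-positive array 1 and 0.46 in array 2, and of 37 tripartite motif genes 13 were higher and 3 lower without overlap, with Trim30a at 1.32. None of these genes passed the threshold after adjustment over all genes. The directions were the same after quantile normalization and with centred medians for the genes named here. In Cre-positive array 1, Il1b (log2 9.49), Cxcl2 (8.84) and Ptgs2 (7.07) stood well above Cre-positive array 2 (6.65, 4.24 and 3.13). The median intensity of 12 spiked-in poly-A control probe sets was 154 in Cre-positive array 2 and 650 to 767 in the other arrays.

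Dim genes were slightly lower in the Cre-positive arrays. Without the filter on dim genes, of 8467 genes at or below the 60th percentile of intensity 5064 were lower and 47 higher at an unadjusted p under 0.05, against 255 lower and 278 higher of 9726 brighter genes. Lower transcription of these genes as the whole cause is argued against by control probe sets for a bacterial gene: all 3 were lower in both Cre-positive arrays, with a median of -0.063, where genes at that level had -0.048. An offset between the arrays at the bottom of the scale may contribute, since it would lower these control probe sets too. After quantile normalization 1486 dim genes were lower at an unadjusted p under 0.05, against 5064 before. This step removes a shared real shift as well, so how much of the pattern the offset accounts for stays open, and real changes of single dim genes stay open.

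Interferon-stimulated genes were higher mostly in Cre-positive array 1. Their median was 1.66 there and 0.30 in Cre-positive array 2, and which of these is typical of the genotype stays open. T and NK cells in its preparation are argued against, because 8 of their markers had a median of 0.011 in array 1 (spread 0.149), against 1.66 for the interferon list. Neutrophils, monocytes or macrophages cannot be told apart from a response of the epithelium itself: 10 of their markers had a median of 0.75 with a spread of 0.73, and S100a8 and S100a9 stood at log2 9.70 and 9.46 in array 1. An effect of the genotype stays open: camera called the list with its preset correlation, but not with an estimated correlation (adjusted p = 0.723). That alternative called no list at all, so its outcome does not decide the question. Without Cre-positive array 1 the list rests on array 2 alone, with its median of 0.30. In array 2 the 13 T and NK cell markers tested had a median of 0.39, MHC class II genes 0.78 and macrophage markers -0.03. T and NK cells were weighed in array 1 only, so their part in array 2 stays open. Separating an effect of the genotype from a stronger colitis in the mouse of Cre-positive array 1 was not tested.

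Reg3b, Reg3g, Pla2g2a, Pla2g5 and Saa1 were lower in both Cre-positive arrays than in both Cre-negative arrays. A smaller share of epithelial cells is argued against, because 13 pan-epithelial markers had a median of 0.15 (spread 0.115), while the least changed of these 5 genes, Saa1, had -1.25. Each of the 5 genes kept at least 98.4% of its difference after quantile normalization. GC-RMA had already made the distributions of the arrays alike, so this step could change little and does not decide whether the scaling between arrays contributed. An effect of the genotype stays open, since these genes passed adjusted over the list alone but not over all genes (limma adjusted p = 0.244 to 0.273). Other differences between the 2 groups of mice were not tested. The list of STAT3 target genes was not called (camera adjusted p = 0.978), but it holds none of these 5 genes and so does not speak to them.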
